A study of Mus musculus with 2 samples.

How the data were processed

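Total RNA of kidney from 2 groups of mice was labelled with biotin and measured on Affymetrix arrays of the 430 2.0 type, 1 array per group. The groups were taken from the sample titles: the control carries normal Invs alleles and the transgene for truncated inversin, and the cystic kidney is homozygous for the inv mutation and carries the same transgene. The series design gives an age of 4 weeks and mentions 2 kidneys, and it was not clear from it how many animals or kidneys gave the RNA of an array. Per the labels, the values came from MAS5, with no version given in the sources used here. The deposited values are an intensity, the linear MAS5 signal of each probe set, and are never negative. The target of the scaling and detection calls were not given in the sources used here.

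The table held 45101 probe sets, of which 64 were control probe sets and were left out, so 45037 remained. The deposited scaling was kept by a preset rule, since the 2% trimmed means of the arrays (178 and 181) differed by 1.83%, narrowly under the limit of 2%. Each array's floor was its median signal over the probe sets that remained, 55.4 for the control and 61.9 for the cystic array. A probe set under the floor on both arrays was treated as not measured. Where it was under the floor on 1 array, that signal was raised to the floor, and the ratio is a bound, given as at least N-fold or named as a bound. For 216 genes the control signal lay between the 2 floors and the cystic signal under its own, which gave values above 0, by at most 0.16, that show no rise. Log2 ratios are cystic minus control. Probe sets were named from the platform annotation, with symbols updated through gene identifiers of a RefSeq table of the GRCm38.p6 mouse assembly, used only for names. Of the probe sets, 34945 named 1 gene, 932 named several and 9160 had no gene named here, and the gene identifiers of 34754 probe sets were found in that table. A gene took the value of the probe set with the highest mean log2 signal among those naming it alone. This gave 18193 named genes, of which 12015 were measured, 10668 on both arrays, 671 on the cystic and 676 on the control array only.

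With 1 array per group no test was possible, and no p-value is given. Genes were counted as changed at a fixed 2-fold difference, and the verbs rose and fell refer to that limit. A bound under 2-fold was not counted, although the difference behind it may be larger. Genes measured by more than 1 probe set gave the only repeat measurement, which is technical and comes from the same RNA. The genes named were fixed by a rule before the data were examined. The rule took the 12 largest differences in each direction among genes above the floor on both arrays and the 5 largest bounds in each direction. From each gene list it took up to 4 members furthest in the direction of the median and up to 2 in the other. It also took all members of lists with under 5 measured members and of the lists for the mutated locus and the sex chromosomes. Predicted transcripts were passed over. Genes named beyond the rule, among them members of gene families and genes whose probe sets disagreed, were chosen after their values were seen. The value of a named gene's second brightest measured probe set, with the floor applied, is printed where it differs by more than 2 times the SD between probe sets or is under 2-fold for a gene past it.

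Before the data were examined, 36 gene lists with 851 members were fixed, for cell types, pathways and neighbouring tissues, and 1 member could not be matched to a gene. For the 31 lists with at least 5 measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. Under the alternatives, 2000 random lists were drawn. These percentiles describe the 2 arrays and are no p-values. A list was called outside the random lists below the 2.5th or above the 97.5th percentile, a limit set after the files were opened and before list values were seen. By it, 16 lists lay above, 8 below and 7 inside. By chance, 1.55 of the 31 would lie outside if the members of a list varied independently of each other. Genes that share a cell type or pathway may vary together, which would put more lists outside.

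The steps were tested on simulated arrays with noise that gave the log2 ratios an SD of 0.3, a setting near the spread between probe sets. The changed genes were drawn from those above the median signal, so the floor was little tested. Noise was independent between probe sets, and differences between animals were not simulated, so the counts do not measure false calls between kidneys. For the cystic against control comparison, over 11596 simulated genes, 100 of 100 genes with a 4-fold change and 6 of 100 with a 1.5-fold change passed 2-fold, as did 9 of 11396 unchanged genes. For the gene list shift, over 11396 genes, 5% of 200 unchanged lists of 25 members lay outside, and 98.5% of lists shifted by 0.3 lay above. On the arrays themselves, 42 spike-in control probe sets had log2 ratios with a median of -0.04 and an SD of 0.17. The ratio of 3' to 5' signal was 0.779 and 0.780 for Gapdh and 1.23 and 1.17 for Actb, control and cystic.

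The alternatives were median centring of the arrays, quantile normalization and cyclic loess in limma (zeros set to 0.1), floors at the 40th and 60th percentile, no floor, a pseudocount of 16, the median over a gene's probe sets, leaving out probe sets marked as shared by their suffix, limits of 1.5-fold and 3-fold, and lists without shared members. After seeing the data, 2 more counts were added, of genes whose second probe set also passed and of genes above the floor on both arrays. A scan of gene families by symbol was also added then. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. No coordinates are given, since no genome build belongs to the array table. Genes read only by probe sets that name several genes or none are not in the gene counts and lists. Such probe sets were counted apart, after the main values had been seen.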

Results

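Gene expression was measured in whole kidney RNA of mice with and without a cystic kidney disease caused by the inv mutation, a mouse model of nephronophthisis type 2. Inversin, the product of Invs, is a protein of the primary cilium. Both kinds of mice carried a transgene that encodes inversin without its C-terminus, fused to green fluorescent protein. The control kidney had normal Invs alleles beside the transgene, and the cystic kidney was homozygous for the inv mutation. Each kind of kidney was measured on 1 Affymetrix array, at an age of 4 weeks by the series design, so the comparison has no replicates and the number of arrays limits its precision. The labels of the cystic array give a female sex and an age of 28 days, and those of the control array give neither. The signal was a linear MAS5 intensity, with a 2% trimmed mean of 178 on the control array and 181 on the cystic array.

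The comparison asks which transcripts differ between the cystic and the control kidney when both carry the truncated transgene. In the cystic kidney, markers of tubular injury, macrophages, fibroblasts and extracellular matrix were higher, with median differences of 2.16, 2.16, 1.57 and 1.54 on the log2 scale. Transporters and enzymes of the proximal tubule were lower, with a median of -1.07, as were genes of amino acid and organic anion metabolism (-1.19) and of fatty acid oxidation (-0.79). Markers of lymphocytes and endothelium had medians of 0.02 and 0.15, inside the range of random gene lists. The highest log2 ratio was that of Lcn2, a secreted iron-carrier binding protein used as a marker of kidney injury, which was at least 83.2-fold higher, and the lowest were those of the enzyme genes Akr1c14 and Acsm3.

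Of 12015 measured genes, 848 (7.06%) were at least 2-fold higher in the cystic kidney and 454 (3.78%) at least 2-fold lower. Among them, 656 higher and 424 lower genes lay above the floor on both arrays, and 192 and 30 were bounds against a signal raised to the floor. At least 4-fold differences were seen for 132 higher and 41 lower genes, and at least 8-fold differences for 27 and 7. Over the 10668 genes above the floor on both arrays, the log2 signals of the arrays had a Pearson correlation of 0.906 across genes, which are not independent replicates. The higher genes made up 65.1% of all genes past 2-fold. With each array centred on its median signal, 609 genes were higher and 672 lower, and the higher share was 47.5%. This centring moved the median log2 ratio of all genes from 0.09 to -0.07, and the percentiles of gene lists below are relative to genes of similar signal. Different probe sets of a gene had a pooled SD of 0.29 in their log2 ratios, over 4694 genes. A second measured probe set was present for 365 of the higher genes and had the same sign in 348 (95.3%), and for 172 of the lower genes it had the same sign in 161 (93.6%). It was itself past 2-fold in that direction in 183 (50.1%) of the 365 and in 100 (58.1%) of the 172.

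**Figure D1:**
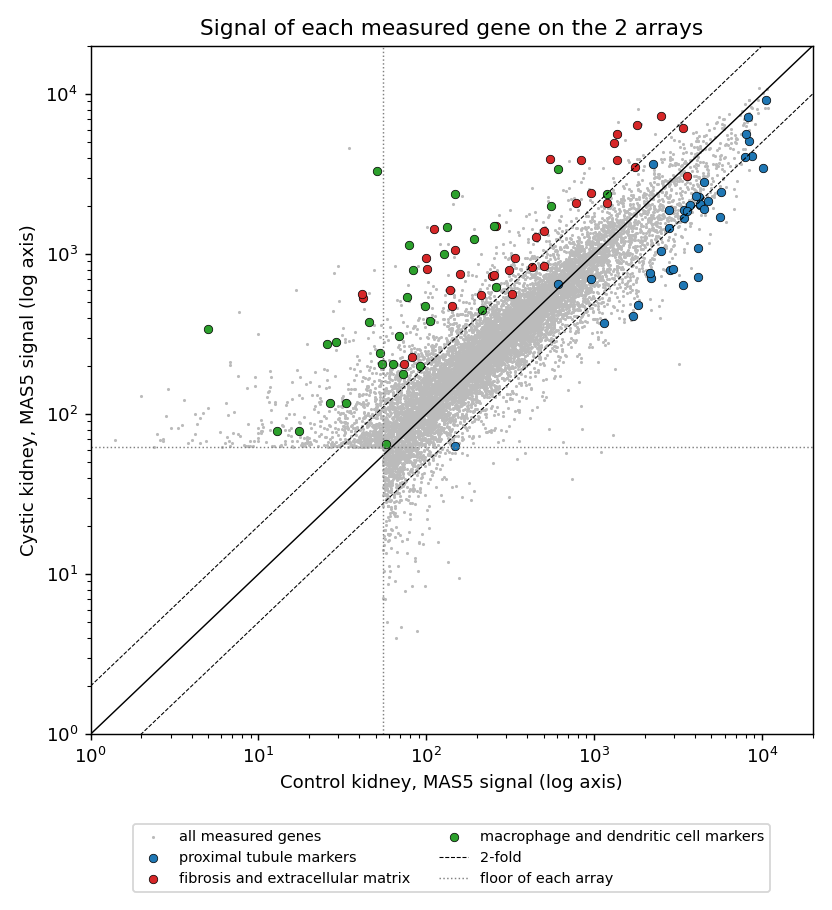
MAS5 signal of each measured gene on the control array (horizontal, log axis) and on the cystic array (vertical, log axis), with 3 gene lists in colour, the floors dotted, 2-fold differences dashed and equality solid. Most matrix and macrophage genes lie above the upper dashed line (28 of 35 and 27 of 31 past 2-fold with the floor applied), and 21 of 37 proximal tubule markers are past 2-fold below equality.

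The mutated gene was read by 3 Invs probe sets. The brightest had a signal of 118 in the control and 15.9 in the cystic kidney, which is under the floor of 61.9 and makes it at least 1.91-fold lower, a bound that leaves open whether the difference passed 2-fold. The other Invs probe sets were under the floor on both arrays, with signals of 36 and 22.1 for one and 5.4 and 54.2 for the other. Which part of the transcript these probe sets read, and whether the transgene carries it, was not examined here. The Tyr probe sets, for the pigmentation gene that the inv insertion carries, were under the floor on both arrays.

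Among genes above the floor on both arrays, Lyz2, which encodes a lysozyme of macrophages, was 16.02-fold higher in the cystic kidney (148 to 2369). Aoc1, a diamine oxidase that degrades histamine, was 14.6-fold higher, and Fgg, the fibrinogen gamma chain, 14.3-fold higher. C1qc and C1qa, subunits of the first complement component, were 14.3-fold and 11.2-fold higher. Tagln, an actin-binding protein of smooth muscle, was 14.0-fold higher, Serpina10 13.2-fold, Col5a2 12.96-fold (second probe set 2.86 in log2) and Col12a1 9.56-fold (second 4.53). Dcdc2a, a doublecortin domain protein, was 12.9-fold higher, with a log2 ratio of 3.69 at its brightest probe set and 1.43 at its second. Tnfrsf12a, the receptor of the cytokine TWEAK, and Mrc1, the macrophage mannose receptor, were each 9.54-fold higher. Of the genes under the floor in the control kidney, Lcn2 (34.7 to 4610.3) was at least 83.2-fold higher, Lyz1 at least 59.9-fold (second 5.21), Npy6r at least 15.3-fold (second 2.54), Havcr1 at least 14.4-fold (second 2.89) and Socs3 at least 13.8-fold. Havcr1 encodes kidney injury molecule 1 and Socs3 a cytokine-induced inhibitor of cytokine signalling. Lyz1 and Lyz2 are near-identical copies whose probes may bind both transcripts, so their separate values are uncertain.

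Acsm3, a medium-chain acyl-CoA synthetase, had the lowest log2 ratio among genes above the floor on both arrays, -4.13 (1290 to 73.9). Slc7a13, an amino acid transporter of the proximal tubule, had a log2 ratio of -3.96 (3182 to 204) and -2.95 at its second probe set. The organic anion transporters Slc22a22, Slc22a7 and Slc22a27 had log2 ratios of -3.39, -2.89 and -2.40. Afmid, an enzyme of tryptophan breakdown, was lower by a log2 ratio of -3.28, with -1.71 at its second probe set. The carboxylesterase Ces1d (-2.79), the glucuronosyltransferase Ugt2b38 (-2.63), the aminoacylase Acy3 (-2.55), the cytochrome P450 Cyp4b1 (-2.40), the enoyl-CoA isomerase Eci3 (-2.37) and Rnf24 (-2.34) followed. Of the genes under the floor in the cystic kidney, Akr1c14 was at least 17.7-fold lower, Slc22a30 at least 11.9-fold, Ces1f at least 10.99-fold, Xist at least 6.25-fold and the glycine methyltransferase Gnmt at least 5.61-fold.

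**Figure D2:**
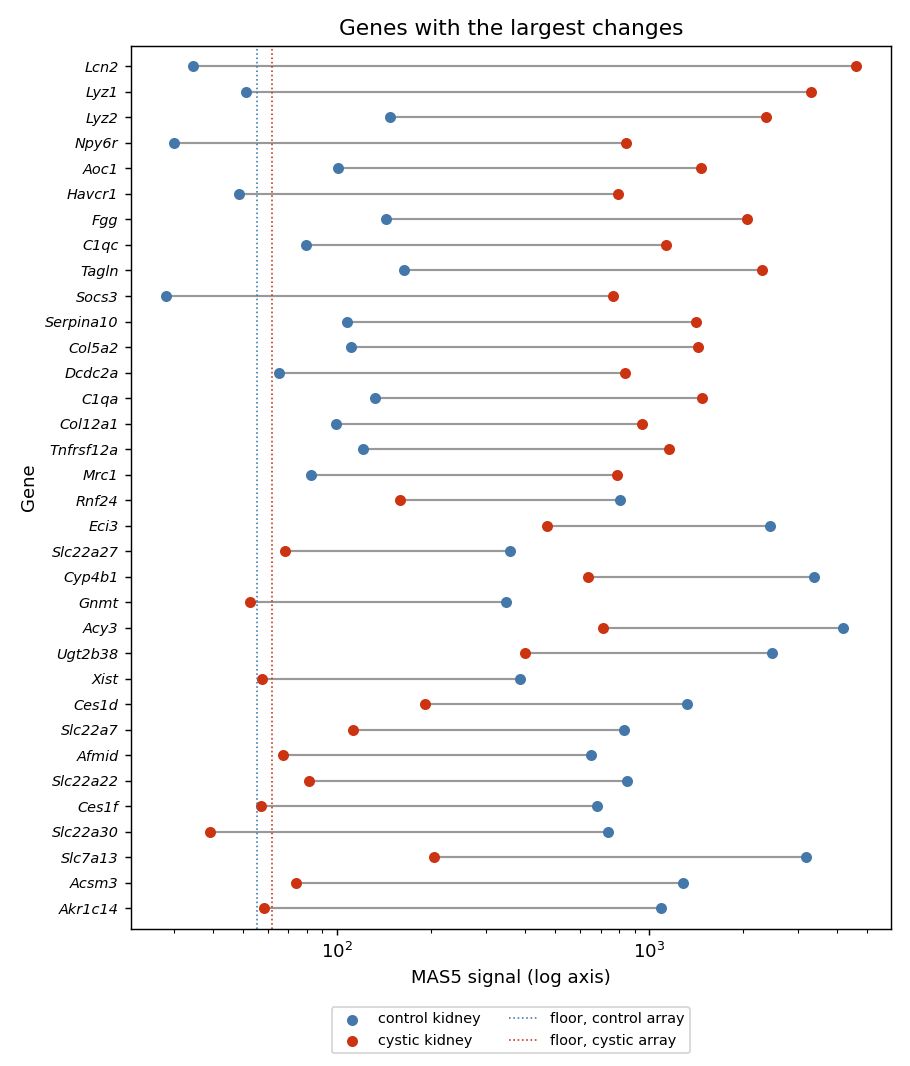
MAS5 signal (log axis) of the genes chosen for the largest differences, with the control kidney in blue, the cystic kidney in red and the floor of each array dotted in its colour. Lcn2 went from 34.7, under the control floor of 55.4, to 4610.3, and Acsm3 from 1290 to 73.9, just above the cystic floor of 61.9.

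Genes of the extracellular matrix were higher as a group. Of 35 measured members, 28 rose at least 2-fold, none fell at least 2-fold, and the median log2 ratio of 1.54 lay above all 10000 random lists of genes with similar signal. Col5a2 had a log2 ratio of 3.70, Col12a1 3.26 and Col1a1 2.85 (second 1.57), and the protease inhibitor Timp1 was at least 10.1-fold and the matrix glycoprotein Tnc at least 9.56-fold higher. The matrix-bound inhibitor Timp3 had a log2 ratio of -0.21. Fibroblast, myofibroblast and smooth muscle markers moved with the matrix: 9 of 13 rose at least 2-fold and none fell, with a median of 1.57, above all random lists. They included Tagln (3.81), Vim (2.46), Acta2, the smooth muscle actin of myofibroblasts (2.42), and Mgp (2.26), while Itga8 had a log2 ratio of -0.07. In TGF-beta and BMP signalling 7 of 20 members rose and none fell, with a median of 0.59, at the 99.97th percentile. Ltbp2 was at least 3.41-fold and Tgfb2 at least 2.95-fold higher, Inhba had a log2 ratio of 1.54, and Tgfb1 had 1.45 at its brightest probe set and -0.12 at its second. Bmp7 and Id2 had log2 ratios of -0.53 (second 0.084) and -0.49.

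Markers of tubular injury and dedifferentiation rose at least 2-fold in 20 of 26 measured members and fell in none, with a median of 2.16, above all random lists. Beside Lcn2, Havcr1 and Fgg, the epithelial keratin Krt19 was at least 7.97-fold higher, and Mmp7 had a log2 ratio of -0.13. Macrophage and dendritic cell markers moved with them: 27 of 31 rose and none fell, with a median of 2.16, above all random lists. Beside Lyz1, Lyz2, C1qc and C1qa, the list's lowest member was Gpnmb, with 0.19. Within this list C1qb had 1.06 at its brightest probe set and 2.85 at its second, and H2-Ab1 1.28 and 3.01. In the list of complement and acute phase genes 6 of 11 rose and none fell, with a median of 1.15, above all random lists. The complement protease Cfi had 3.10, the C1 protease C1s1 2.05, the C1 inhibitor Serping1 1.60, and Serpina3n was at least 7.79-fold higher, while C2 and Cfb had -0.58 and -0.08.

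Chemokine and cytokine genes rose at least 2-fold in 9 of 23 members and fell in none. Their median of 0.53 lay at the 99.91st percentile and was 0.97 with the floor at either the 40th or the 60th percentile and 1.38 with no floor. Ccl9 was at least 5.88-fold higher (second 1.79), Ccl8 had a log2 ratio of 2.37, Ccl6 2.36 (second 1.55) and Il34, a ligand of the macrophage growth factor receptor, 2.32, while Cxcl12 and Il18 had -0.66 and -0.35. Interferon response genes rose in 5 of 21 members and fell in none, with a median of 0.83, above all random lists. The immunoproteasome subunit Psmb8 had 1.99, Gbp2 1.66, the peptide transporter Tap1 1.33 and Ifit2 1.17, while Rsad2 had -0.37 and Usp18 was a bound of -0.26. Lymphocyte markers had no member counted past 2-fold among 6 measured, and a median of 0.02 at the 16.6th percentile, with 5 of the 6 read as bounds, among them Cd22 (0.26), Prf1 (0.24), Pax5 (-0.15) and Cd8a (-0.36). The remaining one, the immunoglobulin gene Ighm, had 0.13 at its brightest probe set and 1.07 at its second. That median was below 0 with median centring (-0.14), quantile normalization (-0.16) and loess (-0.12), and was 0.19 with no floor. Of the neutrophil and mast cell markers only Kit (0.01), Csf3r (0.34) and Ngp were measured, and none was counted past 2-fold; Ngp went from a signal of 60.6 to 48.4, both under the cystic floor, so no direction is read from it.

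**Figure D3:**
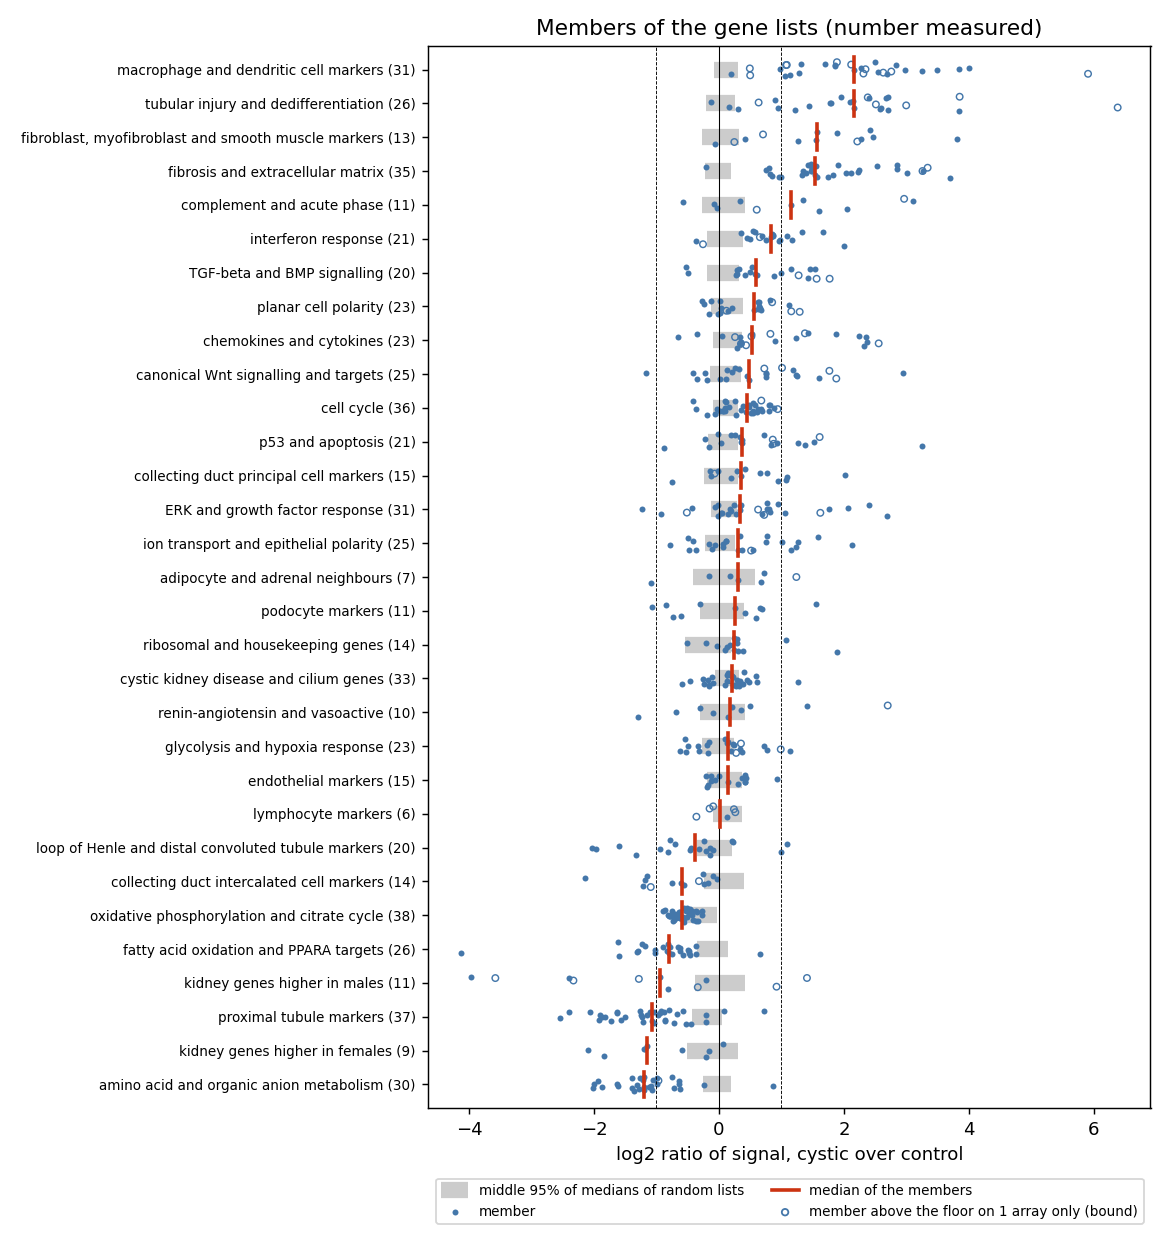
Log2 ratio of signal, cystic over control (horizontal), of each measured member of the 31 gene lists with at least 5 measured members; red bars are medians, open circles are bounds, grey bars hold the middle 95% of medians of 10000 random lists of similar signal, and dashed lines mark 2-fold. The medians run from -1.19 for amino acid and organic anion metabolism to 2.16 for injury and macrophage markers.

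Proximal tubule markers were lower as a group: 21 of 37 fell at least 2-fold and none rose, with a median of -1.07, below all 10000 random lists. Acy3 and Cyp4b1 were followed by Slc22a6, the main organic anion transporter (-2.06), and Slc17a3 (-1.92), while the sulfate transporter Slc13a1 (0.71, and 1.73 at its second probe set) and the glucose transporter Slc5a1 (0.08) were not lower. The list of amino acid and organic anion metabolism fell in 20 of 30 members and rose in none, with a median of -1.19, below all random lists. Akr1c21 went from a signal of 1498 to 374, Inmt had a log2 ratio of -2.01, the sterol demethylase Cyp51 -1.94 and Hpd, of tyrosine breakdown, -1.88, and the vitamin D hydroxylase Cyp24a1 had 0.86. In fatty acid oxidation 9 of 26 members fell and none rose, with a median of -0.79, below all random lists. Acsm3 was followed by Acsm1 (-1.62), the peroxisomal enzyme Ehhadh (-1.60) and the medium-chain dehydrogenase Acadm (-1.32), while Pdk4 had 0.65. All 38 measured genes of oxidative phosphorylation and the citrate cycle had log2 ratios below 0 and none was past 2-fold. Their median was -0.60, at the 0.22nd percentile, and was -0.38 with loess, and Suclg1, Ndufv1, Suclg2 and Ndufs1 had -0.89, -0.86, -0.81 and -0.81. Genes of glycolysis and the hypoxia response had a median of 0.15 at the 89.1st percentile, which was -0.01 with median centring and 0.25 without probe sets marked as shared. Hif1a, the oxygen-regulated transcription factor, rose with 1.14 (second 0.73), Hk2 had a bound of 0.99, Pfkp and Egln3 had 0.77 and 0.72 (second -0.14), and Bnip3 and Car9 had -0.63 and -0.55.

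In the more distal nephron, markers of the loop of Henle and distal convoluted tubule fell in 4 of 20 members and rose in 1, with a median of -0.39 at the 1.19th percentile. The 4 were the calcium binders Calb1 (-2.03, second -2.97) and Pvalb (-1.97), the growth factor Egf (-1.60) and the kallikrein Klk1 (-1.33), and Cldn19, a claudin of the thick limb, rose with 1.10, while Cldn16 had 0.99. Slc12a3 had -0.94, while Slc12a1, Kcnj1 and Umod had -0.32, -0.24 and -0.09. The list joins both segments, so its median does not show which of them was lower. Without probe sets marked as shared, the list's median was -0.24, at the 14.1st percentile. For short, this list of both segments is named the loop of Henle below. Intercalated cell markers of the collecting duct fell in 5 of 14 members and rose in none, with a median of -0.59, at or below the 0.05th percentile in repeated draws of random lists, and of -0.39 with the floor at the 60th percentile. They were led by the anion exchanger Slc4a1 (-2.14), the iodide and bicarbonate transporter Slc26a4 (-1.21), the carbonic anhydrase Car12 (-1.18, second -0.40) and Slc4a9 (-1.16). The smallest differences in this list were those of Hmx2 (-0.04), Atp6v0a4 (-0.10), Atp6v1b1 (-0.18) and Atp6v0d2 (-0.24). Principal cell markers rose in 3 of 15 members and fell in none, with a median of 0.35 at the 98.9th percentile, and of 0.19 with median centring. The 3 were the urea transporter Slc14a2, with 2.01 at its brightest probe set and 0.12 at its second, Gata3 (1.08) and St6gal1 (1.07); the sodium channel subunit Scnn1g had 0.94 and the water channels Aqp3 and Aqp4 -0.75 and -0.15. Podocyte markers had a median of 0.25 at the 86.9th percentile, which was 0.056 with quantile normalization. Tcf21 rose with 1.55 at its brightest probe set and 0.19 at its second, Nphs1, which encodes nephrin, fell with -1.07, and Plce1, Synpo, Cd2ap and Podxl had 0.69, 0.65, 0.59 and -0.85 (second -0.13). Clic5, Ptpro and Vegfa had -0.73, -0.60 and -0.30, and Actn4 and Wt1 had 0.42 and 0.25. The podocyte median therefore stands for members that went both ways. Of 15 endothelial markers none was past 2-fold, and their median of 0.15, at the 66th percentile, was -0.01 with median centring and 0.30 with the median over probe sets; the highest were Eng (0.94), Pecam1 (0.43), Icam2 (0.42) and Tie1 (0.41) and the lowest Esam (-0.21) and Flt1 (-0.19).

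Canonical Wnt genes and targets rose in 8 of 25 members and fell in 1, with a median of 0.48 at the 99.8th percentile, which was 0.32 with median centring and 0.73 without probe sets marked as shared. Myc had a log2 ratio of 2.95 and the receptor Fzd2 1.60 (second 1.01), the Wnt inhibitor Nkd2 was at least 3.67-fold higher, and Wnt4 was at least 3.40-fold higher at its brightest probe set, with a log2 ratio of 0.29 at its second. The Wnt deacylase Notum fell with -1.17, and Sfrp2 had -0.41. Planar cell polarity genes rose in 3 of 23 members and fell in none, with a median of 0.56 at the 99.89th percentile. Ptk7 was at least 2.45-fold and Ankrd6 at least 2.23-fold higher (second 0.78), the giant cadherin Fat4 had a log2 ratio of 1.12 (second 0.64) and its ligand Dchs1 a bound of 0.85, while Wnt11 and Intu had -0.27 and -0.23. Of 33 cystic kidney disease and cilium genes 1 was counted past 2-fold, with a median of 0.21 at the 78.5th percentile, and of 0.049 with median centring. It was Bicc1, an RNA-binding protein whose loss causes kidney cysts in mice, with 1.27. Cys1, Kif3a and Pkhd1, the gene of recessive polycystic kidney disease, had 0.60, 0.59 and 0.49, and Ift88 and Bbs7 -0.59 and -0.46. In the list of ERK and growth factor response 6 of 31 rose and 1 fell, with a median of 0.34 at the 99.2nd percentile, which was 0.18 with median centring and 0.65 with no floor. The immediate early genes Fos, Egr1 and Junb had 2.70, 2.40 and 2.07 and the growth factor Pdgfb 1.76, while Etv5 fell with -1.24 and Fgf1 had -0.93.

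None of 36 cell cycle genes was counted past 2-fold at its brightest probe set, with Kif11 and Bub1 read as bounds of 0.94 and 0.68, while their median of 0.45 lay at the 99.99th percentile. Kif23 had 0.82 and Mcm4 0.80, Top2a had 0.88 at its brightest probe set and -0.19 at its second, and Ccnd1 and Tk1 had -0.41 and -0.37. The second probe sets of Ccnd2 and Racgap1 had 1.16 and 1.03, against 0.46 and 0.54 at their brightest. Without probe sets marked as shared, the list's median was 0.29, at the 95.4th percentile, and it was also 0.29 with median centring. Genes of p53 and apoptosis rose in 5 of 21 members and fell in none, with a median of 0.38 at the 99.2nd percentile, and of 0.22 with median centring. Tnfrsf12a was followed by Casp12 (at least 3.05-fold higher), Pmaip1 (1.51) and Birc3 (1.37), while Bid and Ccng1 had -0.88 and -0.23. In ion transport and epithelial polarity 6 of 25 rose and none fell, led by the claudins Cldn4 (2.14), Cldn7 (1.59) and Cldn3 (1.24) and the chloride channel Ano1 (1.26), while Clcn5 and Fxyd2 had -0.78 and -0.49. That list's median of 0.31 lay at the 99.4th percentile, but was 0.11 at the 74.9th without probe sets marked as shared, 0.16 at the 87.8th with the median over probe sets and 0.15 with median centring. The renin-angiotensin and vasoactive list had a median of 0.18 at the 73.7th percentile, which was 0.016 with median centring and 0.34 with no floor. The vasoconstrictor peptide gene Edn1 was at least 6.50-fold higher, Npr3 rose with 1.41 at its brightest probe set and 0.20 at its second, Ednrb and Nos3 had 0.49 and 0.35, Ace fell with -1.29 and Agtr1a had -0.69.

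Lists fixed to follow neighbouring tissue, blood, housekeeping and sex gave further values. The adipocyte and adrenal list had a median of 0.31 at the 81.1st percentile, which was 0.13 with quantile normalization and 0.51 with the floor at the 60th percentile; Pnmt was at least 2.36-fold higher, Fabp4, Retn and Star had 0.72 (second -0.015), 0.68 and 0.31, the lipase Lpl fell with -1.08 (second -0.58) and Dbh had -0.16. Of the blood list, the platelet factor Pf4 rose with 2.12, Alb had 0.48, Apoa2 a bound of -0.34 and Klf1 -0.87. Ribosomal and housekeeping genes had a median of 0.24 at the 98.9th percentile, and at the 92.3rd without probe sets marked as shared, and it was 0.080 with median centring and 0.51 with loess; Tuba1a and Gusb rose with 1.89 and 1.08 (second 1.69), Ywhaz and Rplp0 had 0.39 and 0.31, and Sdha and Polr2a -0.51 and -0.21. Kidney genes known to be higher in males fell in 5 of 11 members and rose in 1, with a median of -0.95, below all random lists, and those higher in females fell in 5 of 9 and rose in none, with a median of -1.15, below all random lists. In the first, Slc7a13, Slc22a30, Cyp4b1 and Cyp2j13 (at least 5.02-fold lower) were the lowest, Cyp4a12a was at least 2.65-fold higher and Cyp7b1 had a bound of 0.92. In the second, Slc22a19 had -2.10, Slc22a29 -1.84, Slc7a12 -1.21, Cyp4a14 -1.18 and Abcc3 0.06. Xist, the transcript of the inactive X chromosome, had signals of 387 in the control and 57.4 in the cystic kidney at its brightest probe set and of 281.6 and 2.3 at another, and Tsix was under the floor on both arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty were above the floor on both arrays at their brightest probe sets. Usp9y was under it on both (5.2 and 19.1), and the others had log2 ratios of 0.10, 0.36 and -0.06. Their cystic signals were 142, 194 and 198, in the kidney that the labels call female.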

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

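Probe sets outside the gene comparison were looked at only after the main values had been seen. Of 2684 measured probe sets with no gene named here, 125 (4.66%) were at least 2-fold higher in the cystic kidney and 47 (1.75%) at least 2-fold lower. Of 573 that name several genes, 29 (5.06%) were at least 2-fold higher and 24 (4.19%) lower. The shares higher lay below the 7.06% of named genes, and the shares lower lay on either side of their 3.78%. These shares count single probe sets, while those of named genes count each gene once at its brightest probe set, so they are not alike. The probe sets are given only because the gene counts leave them out. The unnamed probe set 1416666_at went from 251 to 1801 (7.17-fold higher), the largest such rise among unnamed probe sets above the floor on both arrays. Unnamed 1424245_at went the other way, from 1110 to 226, a log2 ratio of -2.30.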

How the results depend on the processing

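All alternatives were chosen before the data were examined, except the counts by second probe set and by both arrays above the floor, chosen after the result was seen. Of the genes named by the preset rule, none past 2-fold changed sign under an alternative, and neither did any list outside the random lists. Genes named beyond the rule were not followed one by one. Of genes past 2-fold, 609 to 841 of the 848 higher and 370 to 454 of the 454 lower remained past it under 9 settings of scaling, floor and probe set, and 0 passed 2-fold in the opposite direction. With median centring 609 genes were higher and 672 lower, with quantile normalization 666 and 525, and with loess 700 and 482. A 1.5-fold limit gave 1973 higher and 1297 lower genes, a 3-fold limit 274 and 116, and no floor 2110 and 1694, by construction of the limit or of the genes counted. Counting only genes whose second probe set also passed gave 183 and 100, of the 365 and 172 that had a second measured probe set. Counting only genes above the floor on both arrays gave 656 and 424. Of the values of genes named by the rule under the alternatives, 1608 moved by less than the SD between probe sets of a gene and 159 by more. The 1608 include 201 values from median centring, which moves every ratio by the same amount, less than that SD. Low signal limits what can be read, since 1347 of the 12015 genes were above the floor on 1 array only. Of the 24 lists outside the random lists, 20 to 24 remained outside under each of 9 settings. With median centring all 24 remained by construction, since it subtracts one value from every ratio. The ion transport list was inside with loess, where it lay on the limit, and with 6 other settings, and the loop of Henle, cell cycle and housekeeping lists were inside without shared-suffix probe sets. No paired analysis was possible because each group has 1 array.

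List medians that moved by more than the SD of their random lists were as follows, and apart from median centring, which subtracts one value from every ratio, the cause was not tested. Median centring gave 1.38 for extracellular matrix, 1.41 for fibroblasts, 0.43 for TGF-beta, -1.23 for proximal tubule, -0.55 for the loop of Henle, 0.19 for principal cells, -0.011 for endothelium, 2.00 for injury, 2.00 for macrophages, -0.14 for lymphocytes and 0.37 for chemokines. It also gave 0.67 for interferon, 0.29 for cell cycle, 0.22 for p53, 0.32 for canonical Wnt, 0.40 for planar polarity, 0.049 for cilium genes, 0.18 for ERK, -0.95 for fatty acid oxidation, -0.76 for oxidative phosphorylation, -0.011 for glycolysis, -1.35 for amino acid metabolism and 0.15 for ion transport. Quantile normalization gave -0.91 for proximal tubule, 0.056 for podocytes, 2.01 for macrophages, -0.16 for lymphocytes, 0.36 for chemokines, 0.33 for cell cycle, 0.40 for planar polarity, 0.069 for cilium genes and -0.45 for oxidative phosphorylation. Loess gave -0.87 for proximal tubule, 2.01 for macrophages, -0.12 for lymphocytes, 0.42 for planar polarity, 0.095 for cilium genes, -0.67 for fatty acid oxidation, -0.38 for oxidative phosphorylation and 0.51 for housekeeping genes.

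Without probe sets marked as shared, medians were 1.65 for extracellular matrix, -1.22 for proximal tubule, -0.24 for the loop of Henle, 0 for endothelium, 2.39 for injury, 0.88 for complement, 0.67 for chemokines, 0.29 for cell cycle, 0.52 for p53, 0.73 for canonical Wnt, 0.49 for ERK, 0.11 for ion transport and -1.28 for male-high genes. The median over probe sets gave 0.30 for endothelium, 0.82 for chemokines, 0.52 for p53 and 0.16 for ion transport. The floor at the 40th percentile gave 0.97 for chemokines, and that at the 60th gave 0.97 for chemokines, -0.39 for intercalated cells, 0.064 for podocytes and 1.86 for macrophages. With no floor the medians were 2.40 for injury, 2.38 for macrophages, 0.19 for lymphocytes, 1.57 for complement, 1.38 for chemokines and 0.65 for ERK. A pseudocount of 16 gave 1.99 for macrophages and 0.75 for chemokines, and leaving out members shared with another list gave -0.87 for female-high genes.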

Other observations

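The scan of gene families and all tests in this part were chosen after the result was seen, except the 2 tests with loess. The limits for an even loss and for the Y-linked genes were also revised after their values were seen. Families were taken by the start of the gene symbol, 218 with at least 8 measured members, and set against random lists as for the fixed lists. Of these, 18 lay above and 28 below. By chance, 5.45 would be expected on each side if the members of a family varied independently of each other, which they may not. The signs of the family medians given here were the same with median centring, quantile normalization and loess. The organic ion transporters of the Slc22a family had 15 of 18 members at least 2-fold lower and a median log2 ratio of -1.83, with 7 of them also in fixed lists. Slc22a13 and Slc22a18 had -2.01 and -1.67, and Slc22a15 was at least 2.44-fold higher. Carboxylesterases (Ces, median -0.999, 4 of 8 lower), aldo-keto reductases (Akr, -1.15, 6 of 11 lower), monocarboxylate transporters (Slc16a, -0.81, 4 of 10 lower), aldehyde dehydrogenases (Aldh, -0.62, 5 of 17 lower and 3 higher) and acyl-CoA thioesterases (Acot, -0.64, 4 of 11 lower) were lower as groups. In the Akr family Akr1b8 rose with 1.87. Peroxins (Pex, -0.46) and mitochondrial ribosomal proteins (Mrps, -0.39, and Mrpl, -0.30) had no member counted past 2-fold, while names starting with Rps and Rpl, mostly cytoplasmic ribosomal proteins, had medians of 0.27 and 0.28.

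Annexins had a median of 1.22 with 5 of 8 members at least 2-fold higher, among them Anxa3 (2.70), Anxa1 (2.10), Anxa2 (1.79, second probe set 0.29) and Anxa5 (1.35). Histocompatibility genes (H2-) had a median of 1.02 with 6 of 12 higher, led by the class II gene H2-Aa (2.55), and H2-DMb2 had 1.55. C-type lectin family genes (Clec) had a median of 1.16 with 6 of 11 higher, including Clec4n (at least 4.81-fold, second 0.79) and Clec10a (at least 4.78-fold), while Clec2h fell with -1.78. The secreted proteases named Adamts had a median of 0.64 with 4 of 9 higher, led by Adamts16 (2.53, but 0.076 at its second probe set) and Adamts1 (1.70). Control probe sets for pyruvate carboxylase, an enzyme of gluconeogenesis, were lower in the cystic kidney at each of their 4 positions, for example 1369 to 443 at the 3' end, and the middle probe set for 18S ribosomal RNA went from 1467 to 653.

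The fall of proximal tubule markers was weighed against technical sources. With loess, which removes scaling that depends on signal, their median was -0.87, so such scaling did not account for the whole of it, and the Gapdh ratio of 3' to 5' signal was 1.001 times that of the control, against degradation of the cystic RNA. A lower share of proximal tubule RNA alone would raise the markers of all other cell types alike, but of 8 other cell type lists 2 were below 0 and 5 above by more than the SD of their random lists, from -0.59 for intercalated cells to 2.16 for macrophages, with lymphocytes within it at 0.02 and endothelium, counted above at 0.15, at -0.01 with median centring. The SD over the proximal tubule members was 0.68, more than the 0.44 predicted at most for an even loss from 1.5 times the SD between probe sets, but close to the 0.65 over all measured genes, so such a loss is neither shown nor excluded. A loss of this RNA and a change of expression within the remaining proximal tubule may both be involved, as hypotheses that whole kidney RNA on 1 array per group cannot separate.

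The lower signal of oxidative phosphorylation genes was weighed against signal-dependent scaling. With loess their median went from -0.60 to -0.38, so scaling may account for part of the size. The median lay at the 0.5th percentile of random lists with loess. Those lists are matched on signal and move with the genes under loess, so the percentile could change little and this test decides nothing about it. A link to the fall of proximal tubule genes, whose cells are rich in mitochondria, is open and was not tested.

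The cystic kidney is labelled female, but none of 3 Xist probe sets was above the floor there, the highest at 57.4, while 2 were on the control array. At their brightest probe sets, 3 of the 4 Y-linked genes read here were measured on both (Usp9y was not). Each of the 3 also had a probe set under the floor on both arrays (Eif2s3y 11.1 and 17.9, Kdm5d 5.6 and 3.1, Uty 42.2 and 39.4, control and cystic). These values argue against RNA from a female alone if the Y-linked probe sets bind no other transcripts, which was not examined. The next comparison of these 3 genes rests on the same assumption. Signal of both Xist and Y-linked genes on the control array may come from RNA of both sexes, but the median log2 ratio of these 3, 0.10, lay below the 0.5 set as the least for equal parts by more than the SD of 0.29 between probe sets, although Kdm5d had 0.36 and, at its second probe set, 0.74. A smaller share of female RNA in the control stays open. A sex difference as the only source of the fall of proximal tubule genes would move male-high and female-high kidney genes in opposite directions. Their medians were -0.95 and -1.15. This reading holds only if these genes differ by sex at 4 weeks, which was not examined, so the signs do not decide the question. The male-high list shares Kap, Cyp2e1 and Cyp4b1 with the proximal tubule list. In the female-high list, Slc22a19 (-2.10) and Slc22a29 (-1.84) belong to the Slc22a family, which was lower as a group. A fall with another source can therefore lower both lists whatever the sexes. A sex effect beside such a fall would not show in these signs and stays open. Strain and litter of the mice were not examined here.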
